A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

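The data came from 10 spotted oligonucleotide arrays. Each array was hybridised with amplified, dye-labelled RNA of 1 yeast strain in one channel and of a common reference pool in the other. The strains were tagged Epl1, Epl1 1:380, Epl1 1:485, an eaf1 deletion and Eaf1 1:982, with 2 arrays each. In replicate a the strain was labelled with Cy3 and in replicate b with Cy5. Per the labels, cells were grown to mid-log phase in plates, RNA was amplified with T7 polymerase, and control RNA was added.

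Per the file headers, each raw file holds intensity values per spot, with the mean and median of the signal and of the local background in each channel. The deposited matrix holds log2 ratios of Cy5 over Cy3, which the authors made by print-tip loess on gene probes with a span of 0.4 and no background subtraction, followed by a correction of gene-specific dye bias. The authors left spots that were absent or over a limit of 32768 out of the loess curve. The main results below start from the intensities, and the matrix served as an alternative. The matrix was set against uncorrected intensities after print-tip loess, which is not the processing of the main values. Across gene spots, r ran from 0.719 to 0.996 per array and the slope from 0.552 to 0.995. Genes are not independent replicates, so no p is given.

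Of 15552 spots per array, 2776 were control spots and the others belonged to 6388 gene reporters with 2 spots each. Backgrounds were corrected with normexp (offset 50), and each array was normalised by loess on its gene spots with a span of 0.3. Ratios were turned to strain over pool, and the spots of a reporter and the reporters of a gene were averaged, which gave 6377 features. Of 5315 gene names, 5255 matched a symbol and 54 a synonym in a gene table of the R64 assembly, and 6 matched nothing. That table served for names, codon counts and gene order. The files name no genome build, so no coordinates are given. A gene spot was counted as above background where its signal exceeded the background by 2.6 times the background's standard deviation. In the pool channel 97.6% to 99.2% of gene spots did so. Between 21 and 129 gene spots per array had a Cy5 median above 65000, and no Cy3 median lay there.

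A linear model with 1 coefficient per strain was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 5 residual degrees of freedom and 3.11 prior ones. In 12 comparisons, each strain was set against another strain or against the pool, p-values were adjusted by Benjamini and Hochberg over all features, and a feature was called at an adjusted p under 0.05 and a fold over 1.7. Of 37 gene lists, those with at least 3 measured members were tested by camera, with a preset correlation of 0.01 and with an estimated correlation. A count adjusted over the list alone applied the same limits to the members of the list. Overlaps of calls were tested with Fisher's exact test, two-sided, against the product of the counts over the number of features. For comparisons with a shared control, 100 simulations of unchanged groups gave the correlation and overlap that the control alone produces. Single values were compared with exact permutation tests. Figures were drawn with Python 3.11.15.

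The comparisons, limits, gene lists and rule for naming genes were chosen before the data were examined, except where stated. In each comparison the rule named EAF1 and EPL1, the 10 called genes with the largest rise and the 10 with the largest fall whose arrays did not overlap between strains, and up to 4 called genes per list with several called members or a camera call. Where fewer than 2 members of such a list were called, the 2 with the largest change were taken.

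The alternatives tried were no background correction, plain subtraction with a floor of 1, the pixel median as signal, print-tip loess, median centring, centring on the added RNA controls, the deposited matrix, brighter features only, the brightest reporter of a gene, 1 member per ribosomal protein paralog pair, the replicate letter as a block, trend and robust eBayes, only the groups compared, other limits, and leaving out each array. Centring on added RNA subtracted the median over 8 of 14 added RNA reporters in place of loess. The counts of calls in that setting were planned, but its values for single genes and gene lists were not planned beforehand. Uncorrected intensities with print-tip loess and a fit of named genes alone were added after seeing the data, as were the overlap among named genes alone, the test of a difference of effects and the overlap with the deletion minus Eaf1 1:982.

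The steps were tested on simulated data of 6377 features, with changes added to noise of the size found on the arrays. That noise was drawn independently for each array, while the deviations of the real replicates correlated between strains, as given below. The shares and false calls therefore hold for independent noise and need not hold for these arrays. For Epl1 1:380 against tagged Epl1, 8.96% of 1.5-fold changes, 94.0% of 2-fold changes and 100% of 4-fold changes were called, with 1 false call among 6177 unchanged features. For the deletion against Eaf1 1:982 the shares were 5.97%, 95.5% and 100% with 2 false calls, and against the pool 1.49%, 98.5% and 100% with 2. With nothing changed, tagged Epl1 against the pool gave 0 calls in limma. The replicate letters were not treated as pairs. The deviations of replicate a from b correlated across genes between all 10 pairs of strains, with r from 0.637 to 0.871, and a block for the replicate letter, which is the dye orientation, was run as an alternative.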

Results

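The data were 10 two-channel arrays of budding yeast RNA, 2 for each of 5 strains, and every array set 1 strain against a common reference pool. The strains carried changes in NuA4, the complex that acetylates nucleosomal histones H4 and H2A. Epl1 holds the catalytic subunit Esa1, with Yng2 and Eaf6, in a smaller module known as piccolo NuA4, and Eaf1 is the platform that joins this module to the other subunits. Of the Epl1 strains, 1 carried a FLAG tag on Epl1 with no truncation in its label, and the others carried tagged Epl1 labelled 1:380 or 1:485. These labels were read as the residues kept of a protein of 832 codons. The Eaf1 strains were a deletion and a strain labelled Eaf1 1:982 with an HA tag. The titles of the deletion samples name an HA tag too, while their source label does not, so whether that strain carries a tag is unclear. The label of Eaf1 1:982 calls that strain a C-terminal truncation, yet the EAF1 gene has 982 codons, so the range spans the whole protein. Eaf1 1:982 is treated here as tagged full-length Eaf1, a reading that the labels do not settle. The replicates of a strain, a and b, differed in dye orientation. The labels do not say that they came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Part of this spread followed the replicate letter, which is the dye orientation. Across genes, r between replicates a and b was 0.142 in tagged Epl1 and 0.284 in Eaf1 1:982, and 0.728 to 0.814 in the other strains. Between tagged Epl1 and Eaf1 1:982 it was 0.794 for replicates a and 0.823 for replicates b. The main fit counts such a shared shift as spread.

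The arrays reported on 5315 named genes and 1062 reporters without a gene name, 6377 features in all. Median gene signal ran from 674 to 1086 in Cy5 and from 334 to 585 in Cy3, against local backgrounds of 60 to 74 and 44 to 50. Between 97.8% and 99.4% of gene spots stood above background in the strain channel. The number of arrays limits the precision, and the median half-width of the 95% interval of a difference between strains was 0.26 on the log2 scale. A feature was called when its Benjamini-Hochberg adjusted p in limma was under 0.05 and its fold exceeded 1.7. All values are log2 ratios relative to the bulk of the genes on each array, given with the standard error of the fit and n = 2 arrays per strain.

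The targeted genes were examined first. EAF1 RNA was 4.16-fold lower in the eaf1 deletion than in the pool (log2 change -2.06 ± 0.07, SE, n = 2, adjusted p = 2.918e-06) and 6.44-fold lower than in Eaf1 1:982 (-2.69 ± 0.11). The deletion arrays gave -1.97 and -2.14, and the Eaf1 1:982 arrays gave 0.70 and 0.56. Since the label says that EAF1 is deleted there, the signal left need not be EAF1 RNA. Both folds are therefore lower bounds for the loss. EPL1 RNA was 2.14-fold higher in the eaf1 deletion than in the tagged Epl1 strain (1.10 ± 0.14, adjusted p = 0.00197) and 2.06-fold higher than in the pool. Against Eaf1 1:982 the EPL1 difference was 0.45 ± 0.14 and did not pass the test in the main fit (adjusted p = 0.0735). The size of the rise therefore depends on the control. The deletion lay higher in each replicate, with 1.09 against 0.63 in a and 0.996 against 0.56 in b. Against tagged Epl1, EPL1 changed by 0.41 ± 0.14 in Epl1 1:380, which did not pass the test, and by 0.51 ± 0.14 in Epl1 1:485, which passed it (adjusted p = 0.0400) without reaching the fold limit. Eaf1 1:982 had an EPL1 value of 0.65 ± 0.14 against tagged Epl1 (unadjusted p = 0.00144), which did not pass after adjustment. In replicates a and b, tagged Epl1 stood at 0.03 and -0.14. Epl1 1:380 stood higher in each, at 0.45 and 0.26, as did Eaf1 1:982, at 0.63 and 0.56. The main fit counts a shift shared by a replicate letter as spread, so a failed test here does not show equal EPL1 levels. With the replicate block, no call of EAF1 or EPL1 was gained or lost. The EPL1 differences that failed in the main fit lie under the fold limit and could not be called there. Unchanged calls therefore do not settle whether these differences passed the test, and no p with the block is given for EPL1. The positions of the probes within EPL1 are not given in the sources used here, so these values do not check the truncations. When arrays were centred on the added RNA controls, EAF1 in the deletion against Eaf1 1:982 was -2.43 ± 0.29 with an adjusted p of 0.0509, and EPL1 in the deletion against tagged Epl1 was 1.26 ± 0.25 with an adjusted p of 0.0782. Both calls ended as the standard errors grew while the changes stayed large. EPL1 in the deletion against the pool was then 0.69 ± 0.17, under the fold limit, while EAF1 there kept its call.

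**Figure D1:**
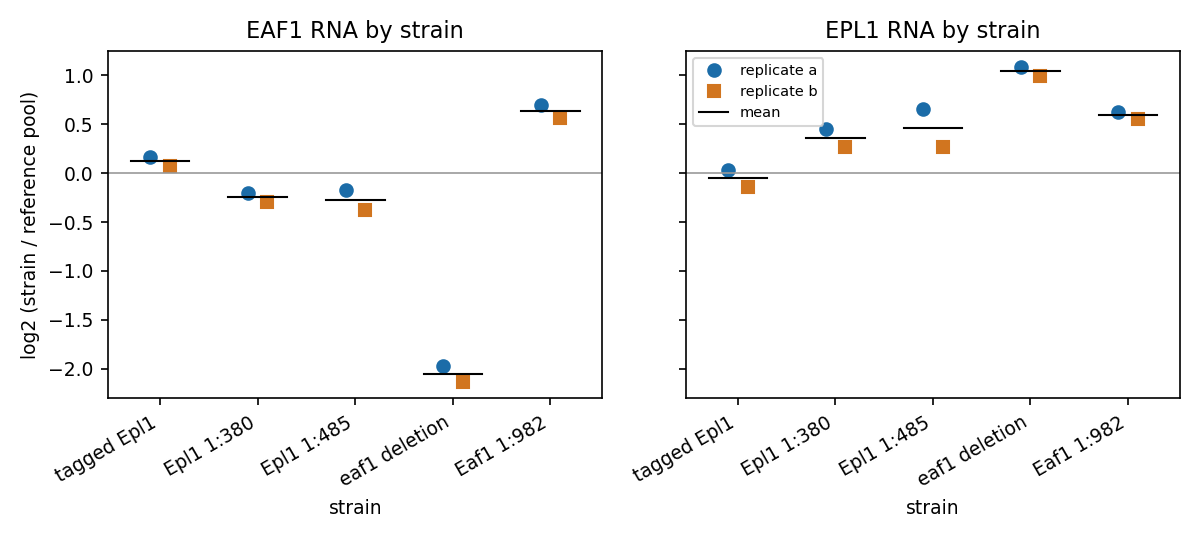
RNA of EAF1 and EPL1 in each strain as log2 ratio to the reference pool. Circles and squares are replicates a and b and the bar is their mean; the EAF1 values of the deletion lie at -1.97 and -2.14, below those of every other strain.

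Both strains with full-length tagged subunits were close to each other and to the pool for most features. Between these strains, the largest difference of any feature was that of EPL1, which was 0.65 higher in Eaf1 1:982. Tagged Epl1 differed from the pool by 13 features (11 higher, 2 lower) and Eaf1 1:982 by 13 (10 higher, 3 lower). The calls were shared for 8 genes, all measured against the same pool. NCE103, the carbonic anhydrase, was 3.23-fold higher in tagged Epl1 (1.69 ± 0.10) and 4.17-fold higher in Eaf1 1:982 (2.06 ± 0.10). PHO84, the high-affinity phosphate transporter, was 4.07-fold lower (-2.03 ± 0.15) and 6.07-fold lower (-2.60 ± 0.15). PYC1, a pyruvate carboxylase, was higher by 1.08 and 1.45. The remaining shared genes were BIO3 and BIO5 of biotin synthesis and uptake, SIP5 and YIG1, all higher, and YLR297W, lower. In limma, no feature was called between Eaf1 1:982 and tagged Epl1, and 54 had an unadjusted p under 0.05 where 319 would be expected by chance. With the replicate letter as a block this count was 276 and the smallest adjusted p was 0.0104, and still no feature passed both limits. Against the pool, NCE103 and PHO84 were the genes picked by the naming rule that kept their calls whichever array was left out. The count of 13 fell to 2 without tagged Epl1 replicate a or b, to 2 without Eaf1 1:982 replicate a and to 3 without its replicate b. Centred on the added RNA controls, the gene median moved by -0.55 in tagged Epl1 and -0.58 in Eaf1 1:982, and 179 and 340 features were then called, nearly all lower. The pool's RNA isolation label differs from that of these strains, so a difference in isolation may enter this shift.

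The comparison of Epl1 1:380 with tagged Epl1 asked what losing the C-terminal part of Epl1 does to the transcriptome. The largest rises included genes of the general stress response. HSP26, a small heat shock protein, rose 12.9-fold (3.69 ± 0.15, adjusted p = 1.817e-05). ALD3, an aldehyde dehydrogenase, rose 6.51-fold (2.70 ± 0.18), HSP12, a membrane-stabilising stress protein, 6.40-fold (2.68 ± 0.24), and HXK1, a hexokinase repressed by glucose, 5.68-fold (2.51 ± 0.18). GPH1, glycogen phosphorylase, CTT1, the cytosolic catalase, DDR2 and MSC1 rose by 2.37, 2.25, 2.20 and 2.10. ARG3, ornithine carbamoyltransferase of arginine synthesis, rose 5.50-fold (2.46 ± 0.10). The largest fall was that of ENB1, the transporter of the siderophore enterobactin, which was 3.92-fold lower (-1.97 ± 0.12). BIO5, a biotin precursor transporter, fell 3.33-fold (-1.74 ± 0.21), and YOL014W, an open reading frame of unknown function, 2.68-fold (-1.42 ± 0.10).

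In total 154 features rose and 69 fell in Epl1 1:380, of which 115 and 66 were named genes. Of the 66 measured targets of the stress factors Msn2 and Msn4, 37 rose over all genes tested and 38 when adjusted over the list alone, and none fell. Their median change was 1.07 (camera adjusted p = 3.641e-29, but adjusted p = 0.0512 with an estimated correlation). Chaperone genes followed in part: HSP42 rose by 2.07 ± 0.14 and SSA4, an inducible Hsp70, by 1.95 ± 0.16, among 4 of 28 that rose, also 4 when adjusted over the list alone. The list's camera adjusted p was 1.093e-05, and its adjusted p = 0.120 with an estimated correlation. Its median of 0.32 was 0.18 under median centring. Cell wall genes rose as well, 10 of 41 (10 when adjusted over the list alone), with PIR3 and SED1 each up by 1.40 and CWP1 by 1.21 (median 0.39, camera adjusted p = 6.718e-09, adjusted p = 0.120 with an estimated correlation).

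Ribosome synthesis moved the other way. Of 129 ribosome biogenesis factors, 127 had negative values and 10 fell (11 when adjusted over the list alone), among them the pre-rRNA processing factors CGR1 (1.99-fold lower) and BRX1 (-0.94 ± 0.09). Their median was -0.48 (camera adjusted p = 3.733e-26, and adjusted p = 0.0306 with an estimated correlation). No subunit of RNA polymerase I or III passed the fold limit, but 23 of 24 had negative values, RPA49 with -0.65 and RPA14 with -0.69 (median -0.45, camera adjusted p = 6.718e-09, adjusted p = 0.120 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.27 with 0 of 127 called (camera adjusted p = 5.302e-14, adjusted p = 0.0825 with an estimated correlation). That median was -0.48 under median centring and -0.12 in the deposited matrix (adjusted p = 0.00598). Mitochondrial ribosomal protein genes rose as a group, with a median of 0.40 over 69 genes and 67 positive values. MRP2 was up by 0.93 ± 0.13 (camera adjusted p = 6.938e-14, adjusted p = 0.00593 with an estimated correlation). These medians kept their sign under median centring and when centred on the added RNA controls.

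Amino acid synthesis was split. ARG3 and ARG8 of the arginine pathway rose (ARG8 with an adjusted p of 0.00170) while HIS4, of histidine synthesis, fell (-0.97 ± 0.12), and the Gcn4 target list as a whole had a median of -0.20, or -0.34 under median centring (camera adjusted p = 0.00191, adjusted p = 0.318 with an estimated correlation). Of its 64 members 3 rose and 2 fell, with the same counts when adjusted over the list alone. The mating pheromone gene MF(ALPHA)1 rose 2.53-fold (1.34 ± 0.14) and the a-factor gene MFA1 1.92-fold (0.94 ± 0.16). RNR3, DDI2 and DDI3, genes induced by DNA damage, rose 1.99-fold, 2.04-fold and 1.96-fold in a list of 25 in which 3 rose over all genes and 3 when adjusted over the list alone (camera adjusted p = 0.00914, adjusted p = 0.120 with an estimated correlation, 0.161 under median centring, 0.108 when centred on the added RNA controls and 0.245 with dim features left out). Of the 64 called genes that the naming rule picked here, which favours large changes, 48 kept their call whichever single array was left out, 29 under median centring and 14 when centred on the added RNA controls. The 14 included HSP26, ALD3, HSP12, HXK1, ARG3, GPH1, CTT1, DDR2, MSC1 and ENB1. The count of 223 features became 105 under median centring (52 up and 53 down) and 39 when centred on the added RNA controls, where the gene median moved by 0.29.

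Epl1 1:485, which keeps more of the protein, was compared with the same control to ask whether the longer fragment has the same RNA profile. HSP26 rose by 3.59 ± 0.15 (adjusted p = 4.562e-05), HSP12 by 2.61 ± 0.24, ALD3 6.06-fold, HXK1 by 2.24 ± 0.18 and ARG3 by 2.13 ± 0.10. RIM4, a translational regulator of meiotic genes, rose by 1.90 ± 0.09. ENB1 fell 4.39-fold (-2.14 ± 0.12), and BIO5 (-1.53 ± 0.21), YOL014W (-1.43 ± 0.10), CDS1, an enzyme of phospholipid synthesis (-1.04 ± 0.09), and HIS4 (-1.03 ± 0.12) fell as well. In all 118 features rose and 44 fell, of which 87 and 43 were named genes.

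Gene groups were examined in Epl1 1:485 as well. Of the Msn2 and Msn4 targets, 34 of 66 rose (36 when adjusted over the list alone), with a median of 0.81 (camera adjusted p = 3.603e-25, adjusted p = 0.0702 with an estimated correlation). Cell wall genes rose for 6 of 41 (6 when adjusted over the list alone), with SED1 up by 1.33 and GSC2, a glucan synthase, by 1.08 (camera adjusted p = 1.056e-07, adjusted p = 0.156 with an estimated correlation). Ribosome biogenesis factors had a median of -0.37 and 125 of 129 negative values, although 1 passed the fold limit (camera adjusted p = 1.063e-20, adjusted p = 0.0520 with an estimated correlation). Mitochondrial ribosomal protein genes had a median of 0.41 with 66 of 69 positive values (camera adjusted p = 1.653e-14, adjusted p = 0.00520 with an estimated correlation). Of the 57 called genes that the naming rule picked, 39 kept their call whichever single array was left out. The count of 162 became 58 under median centring, 252 with plain background subtraction and 19 when centred on the added RNA controls, where the gene median moved by 0.20.

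Set against each other, the truncations did not differ for any feature in limma, and 58 features had an unadjusted p under 0.05 where 319 would be expected by chance. With the replicate letter, which is the dye orientation, as a block, 348 had an unadjusted p under 0.05 and again none was called, so the low count of 58 is no measure of likeness. The largest single difference was 0.48. GPH1 was higher in Epl1 1:380 by 0.41 ± 0.15, GLK1, glucokinase, by 0.39 ± 0.11 and HSP42 by 0.32 ± 0.14, and none of these passed the test. As a group, the Msn2 and Msn4 targets were higher in Epl1 1:380, with 57 of 66 positive values and a median of 0.16 (camera adjusted p = 1.298e-23, adjusted p = 0.120 with an estimated correlation). Ribosome biogenesis factors were lower, with 113 of 129 negative values and a median of -0.08 (camera adjusted p = 1.753e-14, adjusted p = 0.120 with an estimated correlation), a median that became 0.012 when centred on the added RNA controls, below the gene median of 0.09 there (camera adjusted p = 4.643e-12). Without Epl1 1:485 replicate a the ribosome biogenesis value had an adjusted p of 0.238. Against tagged Epl1 the truncations shared 116 of their rises and 41 of their falls (2.85 and 0.476 expected), and r across genes was 0.969. The shared control arrays add to this: a simulation of unchanged groups against the same control gave a mean r of 0.498 and 0.01 shared calls, so part of r itself may come from shared controls, and the observed values lay above the simulated range.

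The eaf1 deletion was compared with Eaf1 1:982 to ask what loss of the platform subunit does. Besides EAF1, the largest changes were rises of PIR3, a cell wall protein, 3.67-fold (1.87 ± 0.21, adjusted p = 0.00146), RIM4, 3.66-fold (1.87 ± 0.09), GPH1, 3.54-fold (1.82 ± 0.15), and HXK1, 3.44-fold (1.78 ± 0.18). AI2, an intron-encoded reading frame of mitochondrial COX1, rose 3.22-fold (1.69 ± 0.19), and SED1, a major cell wall protein, 3.11-fold (1.64 ± 0.18). HSP26 rose 2.62-fold (1.39 ± 0.15). ENB1 again led the falls, 3.24-fold lower (-1.70 ± 0.12), followed by YOL014W (-1.62 ± 0.10), TCB2, a tricalbin of membrane contact sites (-1.23 ± 0.11), RIB4 of riboflavin synthesis (-1.09 ± 0.12) and BDH2, a dehydrogenase (-1.08 ± 0.13). The deletion raised 124 features and lowered 39, and 38 of the rises were reporters without a gene name.

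Among the Msn2 and Msn4 targets, 24 of 66 rose and 1 fell in the deletion, with the same counts when adjusted over the list alone (median 0.66, camera adjusted p = 8.069e-18, adjusted p = 0.107 with an estimated correlation). Cell wall genes rose for 8 of 41 (8 when adjusted over the list alone), including CWP1 by 1.48 and TIP1 by 1.22 (camera adjusted p = 2.441e-10, adjusted p = 0.179 with an estimated correlation). Genes of mitochondrial respiration rose for 5 of 50 (5 when adjusted over the list alone): ATP2 of the ATP synthase by 0.99 ± 0.09, and RIP1, COR1 and CYT1 of complex III by 0.94, 0.94 and 0.93. Their median was 0.41 with 43 positive values (camera adjusted p = 1.357e-10, adjusted p = 0.0873 with an estimated correlation). Mitochondrial ribosomal protein genes had a median of 0.26 (camera adjusted p = 2.809e-08, adjusted p = 0.0222 with an estimated correlation). Ribosome biogenesis factors had a median of -0.29 with 118 of 129 negative values and 1 called, BRX1 at -0.85 (camera adjusted p = 2.098e-15, adjusted p = 0.0873 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.15 (camera adjusted p = 4.863e-05, adjusted p = 0.294 with an estimated correlation), which became 0.036 when centred on the added RNA controls, still below the gene median of 0.27 there (camera adjusted p = 5.795e-06). In the deposited matrix it was -0.06 with an adjusted p of 0.190. Of the 41 called genes that the naming rule picked, 31 kept their call whichever single array was left out and 16 under median centring. Centred on the added RNA controls the gene median moved by 0.27, and in limma no feature was called in place of 163, with 561 at an unadjusted p under 0.05. The count was 42 under median centring and 252 with plain background subtraction.

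Other controls gave related counts for the eaf1 deletion. Against the pool 163 features rose and 69 fell. HSP12 rose 6.02-fold (2.59 ± 0.17), DDR2 4.46-fold (2.16 ± 0.07) and CTT1 4.12-fold (2.04 ± 0.07), and ATP2, COR1 and CYT1 rose by 1.14, 1.13 and 1.08. ENB1 fell by 1.81 ± 0.09 on the log2 scale, and the cell wall mannoproteins FIT2 and FIT3, which help to retain siderophore iron, fell by 1.87 ± 0.23 and 1.19 ± 0.19. Against tagged Epl1 136 features rose and 51 fell, with GPH1 higher by 2.07 ± 0.15 and ENB1 3.42-fold lower (-1.77 ± 0.12). Centred on the added RNA controls, 484 features were called against the pool (72 up and 412 down, gene median -0.32) and 9 against tagged Epl1 (gene median 0.24). Median centring gave 65 calls against tagged Epl1 in place of 187. Epl1 1:380 had 187 features higher and 93 lower than the pool, and Epl1 1:485 had 162 higher and 66 lower, and both sets of values hold the pool's own differences from the control strains. Centred on the added RNA controls these counts became 530 and 714, mostly lower, with gene medians of -0.28 and -0.36, and plain subtraction gave 425 and 351. A difference in RNA isolation between the pool and most strain samples may enter the shifts against the pool.

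**Figure D2:**
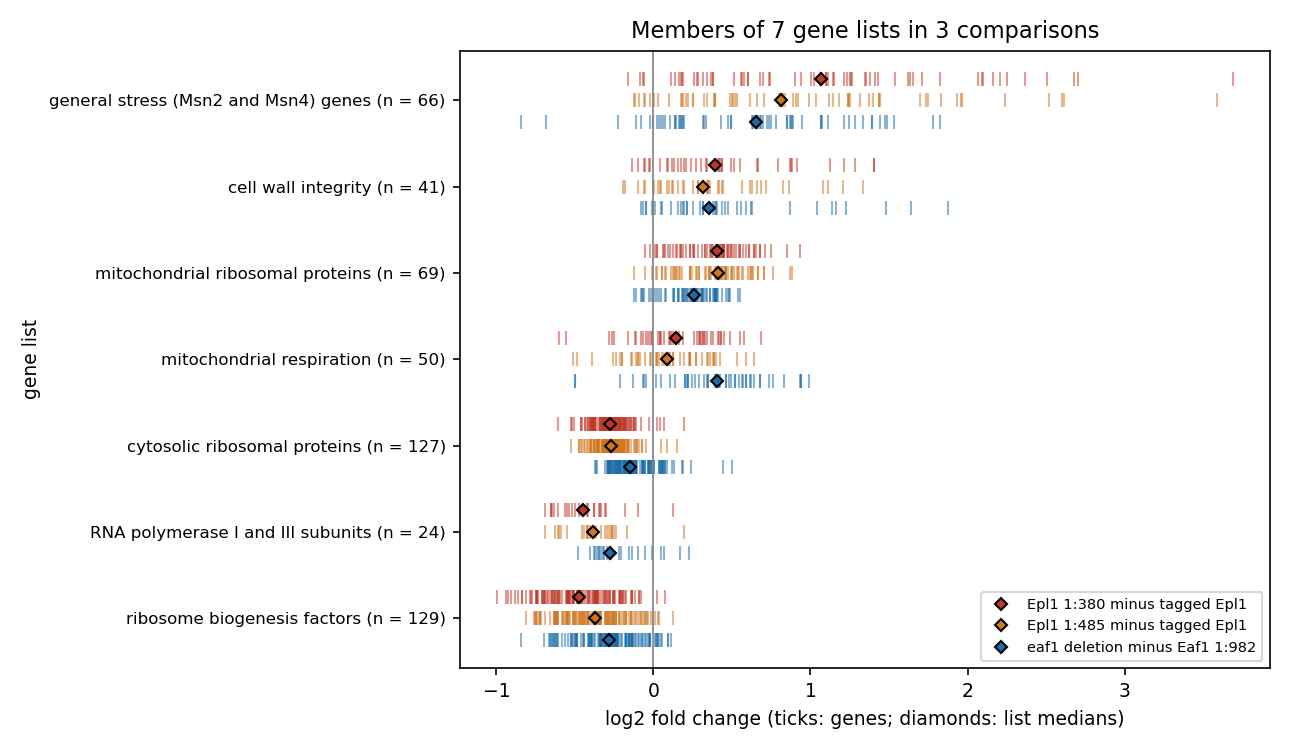
Log2 changes of the members of 7 gene lists in Epl1 1:380 and Epl1 1:485 against tagged Epl1 and in the eaf1 deletion against Eaf1 1:982. Ticks are genes and diamonds list medians; the Msn2 and Msn4 targets have medians of 1.07, 0.81 and 0.66, the ribosome biogenesis factors -0.48, -0.37 and -0.29, and the cytosolic ribosomal proteins -0.27, -0.27 and -0.15, the last of which turned to 0.036 when centred on the added RNA controls, below a gene median of 0.27.

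To ask whether truncated Epl1 and loss of Eaf1 changed the same genes, calls were compared between contrasts that share no arrays. Epl1 1:380 against tagged Epl1 and the deletion against the pool shared 92 rises, where 3.94 would be expected from the product of the counts over all features (Fisher's exact p = 1.688e-117, two-sided), and 23 falls (0.747 expected, p = 8.801e-30). HSP12, DDR2, ALD3, GPH1 and CTT1 were among the shared rises, and ENB1, YOL014W, TCB2 and TMA46 among the shared falls. For Epl1 1:485 the shared counts were 76 (3.02 expected) and 17 (0.476 expected). Against the deletion minus Eaf1 1:982, a pairing chosen after seeing the data, Epl1 1:380 shared 84 rises and 14 falls and Epl1 1:485 shared 68 and 11, and r across genes was 0.748 and 0.740. Genes are not independent replicates, so these r have no p. Fisher's test also counts each feature as independent, so the Fisher p-values overstate the evidence. Many shared rises were reporters without a gene name, 32 of the 84 and 26 of the 68, and such reporters may share signal. Named genes can change together as well, so leaving these reporters out does not remove the overstatement. In a fit of named genes alone, added after seeing the data, Epl1 1:380 shared 52 rises (1.86 expected) and 14 falls with the deletion minus Eaf1 1:982 and 60 rises (2.70 expected) and 23 falls with the deletion minus pool. Epl1 1:485 then shared 42 and 11 with the first and 50 and 17 with the second. No gene was called in opposite directions in these 4 pairs. With Eaf1 1:982 minus pool, the overlap was 1 gene for Epl1 1:380 and 2 for Epl1 1:485, and 2 genes moved in opposite directions. Without Eaf1 1:982 replicate a or b these overlaps were 0 and 1. Under median centring the 4 shared totals of 115, 93, 98 and 79 became 55, 36, 25 and 21.

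**Figure D3:**
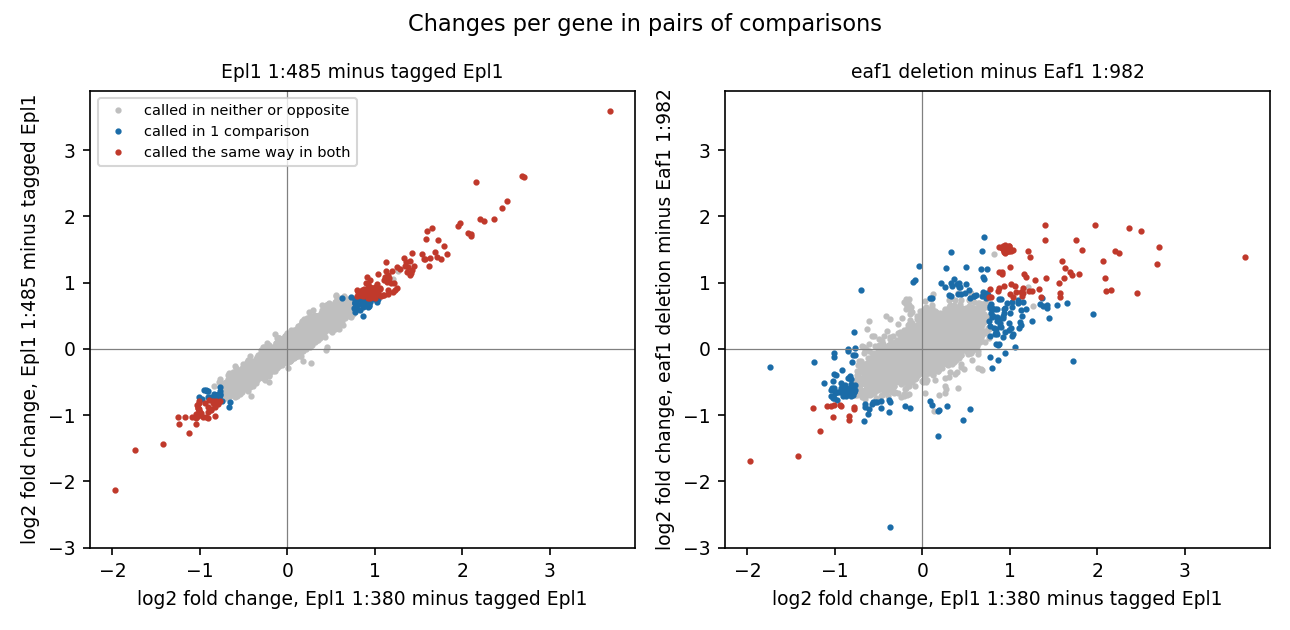
Log2 change of every feature in Epl1 1:380 against tagged Epl1 (horizontal) plotted against Epl1 1:485 minus tagged Epl1 (left) and the eaf1 deletion minus Eaf1 1:982 (right). Red points were called the same way on both axes, 157 at left, where the same tagged Epl1 arrays enter both axes, and 98 at right.

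The eaf1 deletion and Epl1 1:380 were also compared directly. HSP26 was 5.35-fold lower in the deletion than in Epl1 1:380 (-2.42 ± 0.15, adjusted p = 3.500e-04), ARG3 3.42-fold lower (-1.77 ± 0.10) and SNZ3, of vitamin B6 synthesis, 2.06-fold lower (-1.04 ± 0.08). LEU9, of leucine synthesis, was 2.22-fold higher (1.15 ± 0.08) and RNH203, a ribonuclease H subunit, 2.10-fold higher (1.07 ± 0.09). Of the Msn2 and Msn4 targets, 11 of 66 were lower and none higher (12 lower when adjusted over the list alone), with a median of -0.31 (camera adjusted p = 2.396e-11, adjusted p = 0.205 with an estimated correlation). Mitochondrial respiration genes had a median of 0.26 (camera adjusted p = 4.865e-06, adjusted p = 0.205 with an estimated correlation). In total 20 features were higher and 48 lower. The count of 68 fell to 15 without eaf1 deletion replicate a and to 22 without Epl1 1:380 replicate a, to 5 under median centring and to 0 in limma when centred on the added RNA controls, with 138 features at an unadjusted p under 0.05. With plain background subtraction it was 110.

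RNA controls added to the samples were used by the study to look for global changes. The median log2 ratio of the added controls, relative to that of the genes on the same array, was 0.33 and 0.72 on the tagged Epl1 arrays, 0.27 and 0.27 for Epl1 1:380, 0.34 and 0.38 for Epl1 1:485, 0.29 and 0.35 for the eaf1 deletion, and 0.71 and 0.41 for Eaf1 1:982. Every value was positive, so relative to the added RNA each strain had less gene signal than the pool. Only Epl1 1:380 replicate b has the pool's RNA isolation label. On the other arrays this offset cannot be told apart from a difference in isolation. Replicate b of Epl1 1:380 gave 0.27, as replicate a did, but a single array does not settle this. Between strains, 2 arrays against 2 allow an exact two-sided permutation p no lower than 0.333, so no strain can be shown to differ by this test. The replicates of tagged Epl1 and of Eaf1 1:982 stood farther apart than those of the other strains, and both strains serve as controls above.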

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

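The tests in this part were all chosen after the results were seen. The effect of an Epl1 truncation, taken against tagged Epl1, was compared with the effect of the eaf1 deletion, taken against Eaf1 1:982, by testing the difference of the effects in limma. The genes given first are those that the naming rule had picked in either comparison and whose effects differed. HSP26 differed most among the named genes outside the targeted ones: it rose by 3.69 in Epl1 1:380 and by 1.39 in the deletion, a difference of 2.30 ± 0.21 (SE, adjusted p = 0.00577). ARG3 differed by 1.62 (2.46 against 0.84), SSA4 by 1.43 (1.95 against 0.52), MSC1 by 1.22 (2.10 against 0.88) and MCH2, a transporter-like protein, by 0.80 (1.57 against 0.78), all with the larger value in Epl1 1:380. BDH2 differed by 1.55, with 0.47 in the truncation and -1.08 in the deletion. THI4, of thiamine synthesis, differed by 1.01 (0.95 against -0.07), and AAD15, an aryl-alcohol dehydrogenase, by 0.88 (0.09 against -0.79). LEU9 differed by -1.04, with -0.78 in the truncation and 0.26 in the deletion. Other named genes differed too: BIO4, of biotin synthesis, with -1.59 (-0.70 against 0.89), AI1, an intron-encoded frame of mitochondrial COX1, with -1.29 (-0.03 against 1.26), and INH1, an ATP synthase inhibitor, with -1.13 (-0.08 against 1.05). The drug transporter genes PDR15 and PDR5 differed by 1.45 (0.55 against -0.90) and 1.11 (0.19 against -0.92). EAF1 differed by 2.32 (-0.37 against -2.69), and the gene is missing from the deletion strain.

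In total the effects differed for 28 features with Epl1 1:380 (17 higher and 11 lower than the deletion's effect) and for 10 with Epl1 1:485. With the replicate letter as a block these counts were 75 and 71. The test sets 4 strains of 2 arrays each against one another, so its standard errors exceed those of a single comparison. The labels also name different tags, FLAG on Epl1 and HA on Eaf1, with the tag of the deletion strain unclear, and the effect of a tag on these differences was not tested.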

How the results depend on the processing

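The fit without background correction but with print-tip loess and the fit of named genes alone were chosen after seeing the data. So were the overlaps with the deletion minus Eaf1 1:982 or among named genes alone. Values of single genes and gene lists centred on the added RNA controls were not planned beforehand. Counts of calls stayed within 1.5 times their value in all 12 comparisons without background correction, with the pixel median as signal, with print-tip loess, with the deposited matrix, with dim features left out, with the brightest reporter, with the replicate block, with trend and robust eBayes, with only the groups compared, with an unadjusted p under 0.01, and with named genes only. Centred on the added RNA controls, the counts were 39 for Epl1 1:380 and 19 for Epl1 1:485 against tagged Epl1, 0 for the deletion against Eaf1 1:982 (561 at an unadjusted p under 0.05 in limma), 9 against tagged Epl1 and 0 against Epl1 1:380 (138 unadjusted). Against the pool they were 484 for the deletion, 340 for Eaf1 1:982, 179 for tagged Epl1, 530 for Epl1 1:380 and 714 for Epl1 1:485. Under median centring they were 105, 58, 42, 65 and 5 in the first order, and 6 for Eaf1 1:982 and 5 for tagged Epl1 against the pool. The overlaps then were 55 and 36 with the deletion minus pool, 0 and 0 with Eaf1 1:982 minus pool, and 25 and 21 with the deletion minus Eaf1 1:982. With the matrix, the overlap of Epl1 1:485 with Eaf1 1:982 minus pool was 1. Plain subtraction gave 252 for Epl1 1:485 against tagged Epl1, 252 for the deletion against Eaf1 1:982, 110 for the deletion against Epl1 1:380, and, against the pool, 21 for Eaf1 1:982, 20 for tagged Epl1, 425 for Epl1 1:380 and 351 for Epl1 1:485. An adjusted p under 0.01 gave 2 for tagged Epl1 against the pool and 34 for the deletion against Epl1 1:380. Without a fold limit the counts were 1162, 982, 703, 866 and 255 in the first order and 2056, 107, 74, 2517 and 2306 against the pool, because that setting drops a limit. For the other settings the cause was not tested.

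With each array left out in turn, counts ran from 206 to 228 for Epl1 1:380, 135 to 180 for Epl1 1:485, 142 to 163 for the deletion against Eaf1 1:982, 177 to 197 against tagged Epl1 and 15 to 69 against Epl1 1:380. Against the pool they ran from 231 to 268 for the deletion, 2 to 3 for Eaf1 1:982, 2 to 2 for tagged Epl1, 298 to 313 for Epl1 1:380 and 211 to 281 for Epl1 1:485. The overlaps with Eaf1 1:982 minus pool ran from 0 to 2 for Epl1 1:380 and from 1 to 2 for Epl1 1:485. The array that stays alone in its strain is then assumed to vary like the others. That strain is also left in a single dye orientation, so a dye effect of a gene no longer cancels in it. Changes in these counts therefore mix dye effects with dependence on a single array.

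Centring on the added RNA controls moves the values of all genes on an array alike and leaves out loess, and some list medians changed sign with that shift while staying below the gene median: methionine 0.0202, proteasome 0.0272 and ergosterol 0.0584 in Epl1 1:380, iron 0.11 in Epl1 1:485, methionine 0.0681, cytosolic ribosomal proteins 0.0359 and aryl-alcohol dehydrogenases 0.0721 in the deletion against Eaf1 1:982, and ribosome biogenesis 0.0118 and RNA polymerases I and III 0.0443 between the truncations. Tested against the other genes by camera at the preset correlation of 0.01, the adjusted p ran from 4.643e-12 for ribosome biogenesis to 0.0419 for iron. For the polymerases it was 0.0869. Camera with an estimated correlation was not run in that setting. Between the truncations, cytosolic ribosomal proteins were -0.0390 under median centring. With each array left out in turn, that list ran from -0.0328 to 0.0242, mitochondrial respiration from -0.00678 to 0.119 and glycolysis from -0.0464 to 0.249, all negative without Epl1 1:380 replicate b, and glycolysis also without Epl1 1:485 replicate a. With the replicate block, 12 list calls were gained and 1 was lost. With the estimated correlation, 81 camera calls were lost among 180 pairs of a list and a comparison. The 180 include pairs without a call to lose, so the share of calls lost was larger than 81 in 180. A block for slides was not run, since the files name no slides. Signal over background limits the dimmest spots, and leaving out dim features moved no count by over 1.5 times.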

Other observations

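The tests in this part were all chosen after the results were seen. The 19 measured genes of the mitochondrial genome had a median above the pool in every strain: 0.66 in the eaf1 deletion, 0.39 in Epl1 1:380, 0.38 in Epl1 1:485, 0.30 in tagged Epl1 and 0.14 in Eaf1 1:982. The median of the deletion against Eaf1 1:982 was 0.45, while those of the nuclear chromosomes in that comparison ran from -0.04 to 0.04. No test of these genes as a group was run. In the same comparison 3 reading frames of Ty retrotransposons rose, which were picked after their values were seen, and no list of such frames was tested: YPR158W-A by 1.52 ± 0.19 (adjusted p = 0.00217), YDR210C-C by 1.45 ± 0.14 and YMR046C by 1.21 ± 0.16 (SE, n = 2 arrays per strain). Their values in Epl1 1:380 against tagged Epl1 were 0.92, 0.95 and 0.67, so higher values were not particular to the deletion.

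Among the rises of the eaf1 deletion were 38 reporters without a gene name, with a median of 1.49 and quartiles of 1.14 and 1.52. They were bright, with a median log2 intensity of 12.7 against 9.23 for all features. Other reporters matched on intensity had a median change of 0.01 (0.00683). They were drawn only from features not called in this comparison, which holds their median near 0. A bias of bright spots therefore stays open. The differences between replicates a and b correlated among the 38 with a median r of 0.84, above 100% of 1000 matched sets, whose 95th percentile was 0.111, so the reporters may share signal as copies of a repeat would and need not be 38 separate genes. Of these reporters 32 also rose in Epl1 1:380 and 26 in Epl1 1:485, with medians of 0.95 and 0.80, and no biological explanation was tested.

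The 8 genes called against the pool in both full-length tagged strains, among them NCE103 and PHO84, lay on the same side of 0 in 83.3% of the gene and array pairs of the other 3 strains. A property of the pool's RNA and a feature that these strains have in common cannot be told apart, since every array holds the same pool. BIO3 and BIO5 lay on the other side of 0 in the Epl1 truncations. The pool and Epl1 1:380 replicate b have the same RNA isolation label, which the other strain samples do not carry. The median size of the 8 changes on that replicate was 1.05 times that on replicate a. This is a single array, which also differs in dye orientation and whose label is the odd one of its strain, so an effect of the isolation stays open.

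EPL1 was higher in the eaf1 deletion than in tagged Epl1 by 1.10. It was higher by 0.45 than in Eaf1 1:982, which did not pass the test in the main fit, although each replicate lay higher. The 20 measured genes next to EPL1 had a median change of 0.05 (0.0454), with a range from -0.49 to 0.70, and the 112 genes of the chromosome had a median of 0.01, which argues against an extra copy of the region. The tagged gene in the control strain may differ in RNA level from the untagged gene for reasons that stay open. Tagged Epl1 itself stood at -0.05 against the pool, and Eaf1 1:982 stood at 0.59.

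The added RNA controls, relative to the genes, had a mean of 0.54 over the strains treated as full-length and of 0.32 over the other 3 strains. The difference was 0.23. The grouping was made from these values, so no p is given for it, and an exact permutation of the 5 strains, with 10 splits, could not give one under 0.1.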
